A study of Mus musculus with 15 samples.

How the data were processed

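Single-cell RNA libraries were prepared from mouse bone marrow cells selected for the stem cell factor receptor Kit after depletion of mature blood lineages. The labels list 15 samples. Of these, 5 are fresh H2BHiMMPLo libraries, 5 are fresh H2BLoMMPLo libraries, and 5 are libraries of cultured cells named G1, G2, G3, G4 and LSK-SLAM. The labels expand none of these codes, so they are used here as given. G1 and G3 also stand in the titles of some fresh libraries, but the labels do not state that the cultured G1 and G3 cells are the same populations. Fresh libraries were made with 10x Chromium 3' version 3.1 chemistry and cultured libraries with version 4 chemistry, per the labels, so fresh and cultured libraries were not compared. The labels describe pooled animals and do not say that replicates came from separate animals. The p-values therefore measure the spread between libraries, which may be technical.

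The deposited matrices hold UMI counts per gene and cell, whole numbers that the authors had not normalised. Per the submitters' processing notes, Cell Ranger 6.1.2 produced them against mm10. The authors' cell label file gives 1 type name to each of 119132 cells in 11 libraries and 32 types, and the tool that assigned the names is not stated. A library of 8411 cells in that file could be tied to no sample and was not used, which left 110721 cells. Count matrices of H2BHiMMPLo replicates 2, 3 and 5, of H2BLoMMPLo replicates 1, 2, 4 and 5, and of cultured G1 to G4 were used. For H2BHiMMPLo replicates 1 and 4, H2BLoMMPLo replicate 3 and the cultured LSK-SLAM library, expression was not analysed here, but the authors' cell labels of the fresh libraries among them entered the shares of types. Each matrix has 28692 genes. Genes were matched by Ensembl identifier because 58 symbols are shared by more than 1 identifier. Positions are those of GENCODE release 21 on GRCm38, counted from 1.

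In the fresh libraries, barcodes with an authors' type name were used. They held 142958775 to 215052840 UMIs per library, with a median of 15005.5 to 23414 UMIs per cell. Barcodes without a type name held a median of 1053 to 1615.5 UMIs, of which 66.5 to 88.5% were mitochondrial, against 0.92 to 2.53% in the cells used. Every fresh library exceeds, in UMIs alone, the read depth that the labels give as the target. In the cultured libraries, cells with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs were used, which left 2484, 762, 2673 and 2094 cells of G1, G2, G3 and G4. Scrublet, in scanpy 1.11.5, then removed 16, 2, 8 and 3 of these as doublets. In fresh libraries, the threshold that Scrublet sets itself marked only 6, 2 and 7 cells in H2BHiMMPLo replicate 5 and H2BLoMMPLo replicates 4 and 5, so an alternative removed the cells with the highest scores, 0.8% per 1000 cells. Intervals on shares of cells are exact binomial (Clopper-Pearson) and intervals on CPM are exact Poisson, both at 95%, and they cover counting error only.

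UMI counts were summed per library over all annotated cells and over each type with at least 25 cells in at least 2 libraries per group. H2BLoMMPLo was compared with H2BHiMMPLo by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and the name series as a covariate. The name series is the JB or G at the start of the bracketed code in a library's title, and 6 fresh libraries are JB and 4 are G. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, within each set of cells. Fold changes are given as log2 of H2BLoMMPLo over H2BHiMMPLo, with a standard error (SE) derived from the fitted fold change and its F statistic. The stem cell type was chosen as the type with the highest mean expression of a stem cell gene list, which was HSCP (mean log2 CPM of 5.197, against 3.739 in MKP, the next type). 36 fixed gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, where at least 5 members were measured. Shares of types were compared over all 10 fresh libraries by a two-sided exact permutation test. Residual degrees of freedom were 4 for all cells and 3 for HSCP. Cultured conditions had 1 library each, so no test between them was made. Their UMI sums were compared as log2 ratios of CPM + 1, and the median of each list was placed among 10000 random lists matched for expression. Leiden clusters (resolution 0.5) of the cultured cells were used to compare lists within clusters. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

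The groups, tests, filters, gene lists, alternatives (except those named below) and the rule for naming genes were fixed before the data were examined. By that rule, the genes named in all cells and in HSCP are up to 10 per direction that passed and separated the libraries of the groups, and up to 3 per direction in other types. Where fewer than 5 passed, the 5 with the smallest p are named as not passing. Up to 4 members of each list with the smallest p are named too, as are the members with the largest fold change of the lists changed most, and, in culture, the genes with the 10 highest and 10 lowest ratios of G3 to G1 and the extreme members of each cell type list. Gene models without a symbol are left out of the names. The text prints part of the genes that the rule names, and the tables hold the others. The values of 1 gene, and the share of 1 type in the search for libraries that stand apart, are not reported here. Other named genes are members of the fixed lists or of counts of called genes and were chosen after their values were seen.

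Whether replicate numbers pair the libraries was checked by the correlation, across types or genes, of libraries that share a number. The correlation of shares across types was 0.66, 0.87, 0.59, 0.77 and 0.83 for numbers 1 to 5, and -0.43 to -0.77 once the mean of each name series was removed. Removing the means of so few libraries by itself tends to make such values negative, so they decide nothing about pairing. The covariate was the name series, as fixed beforehand. The replicate number as a block was run as an alternative. Other alternatives were DESeq2 1.42.0, RLE factors in edgeR, no filter on low counts, no covariate, doublets removed, other cell minimums, equal weight per type, camera with an estimated correlation, fry, other scales and tests for shares, and each library left out in turn. Alternatives chosen after the data were seen were the removal of cells with the highest doublet scores, of cells with an Xist UMI and of cells with over 50 S100a8 UMIs in types other than neutrophils and monocytes, and fits within JB and within G.

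The procedure was tested on simulated data with the same libraries. In all cells, 68.7% of genes raised or lowered by 1 log2 unit and 88.9% of genes changed by 2 units were recovered, with 10 false calls of 166. In HSCP these shares were 74.7 and 99%, with 18 false calls of 190. DESeq2 made 54 false calls in all cells and 2 in HSCP. Genes were drawn independently around a common mean for all libraries, with no difference between name series. Real changes may therefore be recovered less often than these shares state. Of 8 types with a share changed 1.5-fold, 8 were recovered with 0 false calls, with counting error as the one source of spread. The 8 were changed together, and a single changed type could not have passed the adjustment over types. A cultured list raised by 1 log2 unit gave a median of 0.98.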

Results

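The libraries hold blood stem and progenitor cells of mouse bone marrow, and the question put to them was how cells of the H2BHiMMPLo and H2BLoMMPLo populations differ in cell types and in gene expression. The 10 fresh libraries held 5561 to 19212 cells with an authors' type name, of 32 types from the stem and multipotent HSCP cells to immature neutrophils (immNeu). Expression was measured in 28171 cells of 3 H2BHiMMPLo libraries and 32020 cells of 4 H2BLoMMPLo libraries. The cultured conditions G1, G2, G3 and G4 were measured in 1 library each.

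Late neutrophil precursors (preNeu-3) were the most frequent type in both populations, with 20.5% ± 8.06 of cells in H2BHiMMPLo and 22.1% ± 8.24 in H2BLoMMPLo (mean and SD, n = 5 each). HSCP cells made up 2.20% ± 1.01 and 1.75% ± 1.42, megakaryocyte progenitors (MKP) 5.04% ± 2.93 and 3.78% ± 3.04, and the earliest erythroid progenitors (ERP1) 6.37% ± 4.17 and 5.65% ± 3.82. The lowest p-values belonged to Macrophage cells, at 0.253% ± 0.127 and 0.613% ± 0.540 (exact permutation p = 0.103), and to Mono cells, at 2.36% ± 0.491 and 3.13% ± 0.794 (exact permutation p = 0.111). Within the JB libraries the Macrophage difference was 0.0894 percentage points, and within the G libraries it was 0.764. Over the libraries measured, Macrophage cells held medians from 1003 UMIs (H2BHiMMPLo replicate 2) to 1742.5 UMIs (H2BLoMMPLo replicate 2). Barcodes without a type name held medians of 1053 to 1615.5, and all cells used 15005.5 to 23414. How far the Macrophage share depends on which barcodes were given a type name was not tested. None of the 32 shares passed (0 types at an unadjusted p under 0.05, lowest adjusted p = 0.976). The exact permutation test over 252 splits could have given an unadjusted p of 0.0079 at the lowest. In a single type that p would not pass adjustment over 32 types, so only several types changed together could have been called. Permuting within the name series gave 0 types as well, and so did edgeR on the counts of cells (lowest adjusted p = 0.448).

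The shares followed the name series of the libraries instead. Immature neutrophils made up 2.37% ± 0.583 of cells in the 6 JB libraries and 19.2% ± 6.0 in the 4 G libraries, and preNeu-3 cells 15.8% and 29.6%. Stem and early progenitor types were scarcer in G libraries: HSCP made up 2.77% ± 0.590 of JB cells and 0.783% ± 0.680 of G cells, ERP1 8.76% and 1.88%, Multi-Lin-2 9.36% and 2.47%, MKP 6.33% and 1.54%, and the multipotent MPP4 cells 3.55% and 0.673%. In all, 17 of 32 types differed at an adjusted p under 0.05 (two-sided exact permutation test over 210 splits, smallest possible p = 0.0048). For MPP4 the adjusted p was 0.0127 and for MKP 0.0218. Both series hold both populations, so the name series was the covariate of expression, except in DC cells, where every library was JB.

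**Figure D1:**
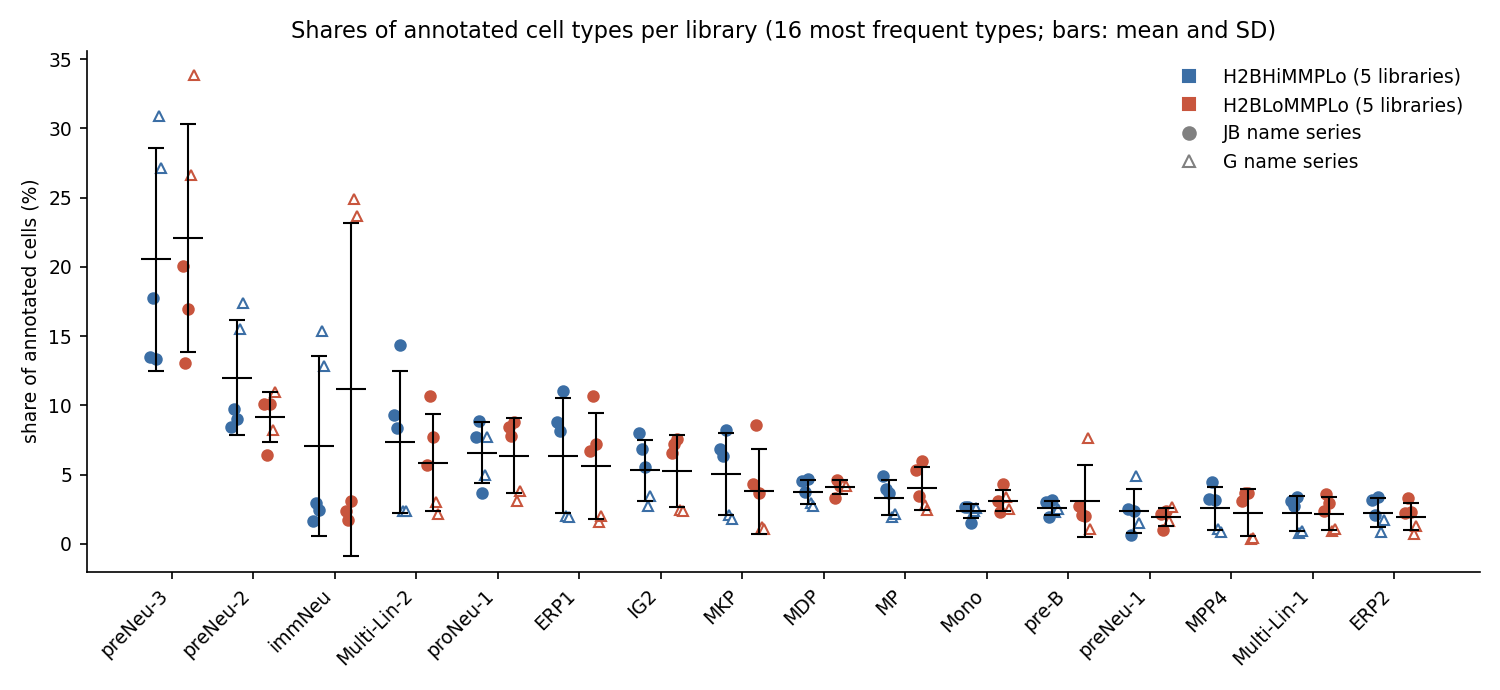
Share of annotated cells (percent, y axis) for the 16 most frequent types, in H2BHiMMPLo and H2BLoMMPLo libraries (5 each). Points are libraries (circles JB, triangles G) and bars the mean and SD. The populations overlap in every type shown, while the immNeu shares of G libraries (mean 19.2%) lie far above those of JB libraries (mean 2.37%).

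In all annotated cells, 3 of the 5 genes with the smallest p were early response genes, Btg2, Zfp36 and Fosb, that a stimulus induces within minutes. Btg2, an antiproliferative gene (chromosome 1, 134075170 to 134079120, minus strand), had a log2 fold change of 0.55 (SE 0.07) in H2BLoMMPLo over H2BHiMMPLo, from a log2 CPM of 4.65 ± 0.22 (SD, n = 3) to 5.27 ± 0.25 (n = 4), and every H2BLoMMPLo library lay above every H2BHiMMPLo library. Zfp36, whose protein speeds the decay of inflammatory mRNAs, had a log2 fold change of 0.59 (SE 0.08), and Fosb, a subunit of the transcription factor AP-1, one of 1.00 (SE 0.15). Other AP-1 and early response genes were also higher: Fos by 1.02 (SE 0.17, all 4 H2BLoMMPLo libraries above all 3 others), Jun by 0.73 (SE 0.13), Egr1 by 0.77 (SE 0.17) and Klf2 by 0.62 (SE 0.16). Within JB libraries alone the log2 fold change was 0.51 for Btg2 in all annotated c-Kit cells and 1.19 for Fos in all annotated c-Kit cells, and within G libraries 0.60 and 0.75. The other 2 genes were lower: Dnah8, a dynein heavy chain gene, had a log2 fold change of -0.43 (SE 0.07) and Islr, a gene of stromal cells, one of -1.57 (SE 0.26). None of these passed: edgeR called 0 of 14718 genes, with 292 at an unadjusted p under 0.05 where 736 would be expected by chance, and DESeq2 called 10 genes higher and 5 lower. The smallest adjusted p in edgeR was 0.833, for Btg2 and Zfp36.

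**Figure D2:**
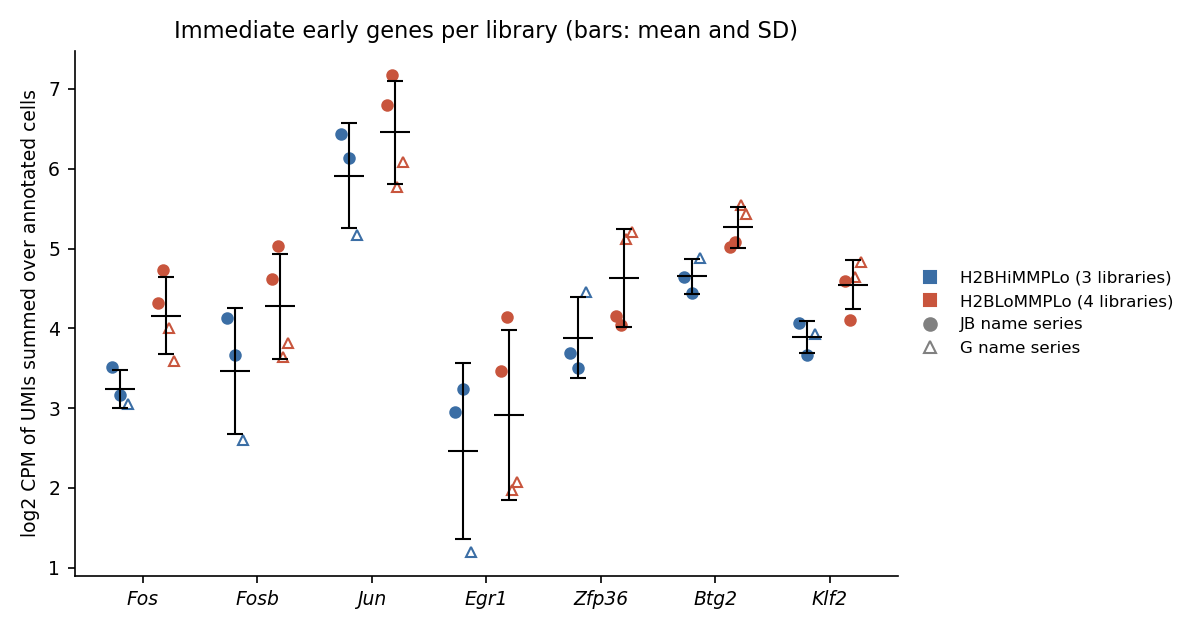
Expression (log2 CPM, y axis) of 7 early response genes in all annotated cells of each library, with 3 H2BHiMMPLo and 4 H2BLoMMPLo libraries. Points are libraries and bars the mean and SD. For Fos the means are 3.24 and 4.16 and for Btg2 4.65 and 5.27, with every H2BLoMMPLo library above every H2BHiMMPLo library for these genes.

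As a group, the genes that cell dissociation and other stimuli induce were higher in H2BLoMMPLo, with 15 of 22 members above 0, a median log2 fold change of 0.38 and an adjusted p of 1.66e-13 by camera (0.195 with an estimated correlation). Adjusted over the list alone 9 of its genes passed, against 0 over all genes tested. The list's 14 early response members were all above 0 (median 0.60), while 1 of its 8 heat shock members was (median -0.13, and 0.14 without H2BHiMMPLo replicate 5). Monocyte and macrophage genes were higher in 19 of 19 members (median 0.31, adjusted p = 6.05e-14, and 0.257 with an estimated correlation), with the complement genes C1qa at 1.10 and C1qc at 1.07. This value was not separated from the mean shares of Macrophage and Mono cells, which were larger in H2BLoMMPLo without passing. The list was called higher in 11 of 23 single types and had a median of -0.04 in HSCP cells (adjusted p = 0.744). Interferon response genes had a median of 0.21 with 26 of 28 above 0 (adjusted p = 4.16e-11, and 0.222 with an estimated correlation), and among them Rsad2 and Zbp1, sensors and effectors of viral infection, stood at 0.74 (SE 0.19) and 0.45 (SE 0.10). Genes of quiescence and cell cycle inhibition had a median of 0.13 (adjusted p = 4.84e-06, and 0.195 with an estimated correlation; 3 genes adjusted over the list alone), and NF-kB targets, led by the chemokine genes Cxcl2 at 1.84 and Ccl3 at 0.76, a median of 0.18 (adjusted p = 2.43e-05, and 0.195 with an estimated correlation). The mean of the interferon, quiescence and NF-kB lists was higher in 4 of 4 H2BLoMMPLo libraries than in every H2BHiMMPLo library. Egr1 and Nr4a1 are in both the quiescence and the dissociation list, so the calls of these lists are not fully separate.

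Genes of cell division were lower in H2BLoMMPLo by small amounts. None of the 25 G2M genes was above 0 (median -0.07, adjusted p = 3.96e-08 by camera, and 0.415 with an estimated correlation), with Top2a, the topoisomerase of dividing cells, at -0.17 and Kif11 at -0.15. S phase genes had a median of -0.07 (adjusted p = 2.43e-05, and 0.415 with an estimated correlation). Stem cell genes were also lower (6 of 25 above 0, median -0.11, adjusted p = 0.0078, and 0.594 with an estimated correlation), with Hlf, a transcription factor gene of stem cells, at -0.35 (SE 0.14) and Ly6a, which encodes the antigen Sca-1, on the other side at 0.71 (SE 0.33). Of genes tied to metabolism, the 13 mitochondrially encoded genes were all below 0 (median -0.17, adjusted p = 0.000675, and 0.594 with an estimated correlation), ribosomal protein genes had a median of -0.04 (adjusted p = 0.000446, and 0.594 with an estimated correlation), lysosome genes one of 0.07 (adjusted p = 3.37e-05, and 0.477 with an estimated correlation) and genes of cholesterol and fatty acid synthesis one of 0.075 (adjusted p = 0.0211, and 0.594 with an estimated correlation). Nuclear genes of oxidative phosphorylation (median -0.02, adjusted p = 0.257), glycolysis (0.03, adjusted p = 0.473), the TCA cycle (-0.01, adjusted p = 0.57), fatty acid oxidation (0.00, adjusted p = 0.673), mTORC1 and amino acid transport (0.02, adjusted p = 0.415) and autophagy (0.04, adjusted p = 0.137) were not called. MHC genes (0.10, adjusted p = 0.00126, and 0.195 with an estimated correlation) and T and NK cell genes (0.63, adjusted p = 0.0179, and 0.594 with an estimated correlation) were called higher. The T and NK list was measured in 2 single types and called in 0, and 1.17% of cells in H2BLoMMPLo replicate 1 were named Regulatory T cell, against at most 0.349% in the other H2BLoMMPLo libraries.

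In total, 15 of 36 lists were called in all cells, 10 higher and 5 lower, and 0 with an estimated correlation or with fry. The genes associated with ageing of stem cells were called higher (adjusted p = 0.0348, and 0.594 with an estimated correlation; 3 genes adjusted over the list alone) although their median was -0.02 and their mean 0.08. Fos, Jun and Junb are in this list and in the dissociation list. Among lists not called, the erythroid genes had a median of -0.14 and a mean of 0.28, with Hba-a1 at 1.33 (SE 0.24), and the lists of mitochondrial dynamics, basophil and mast cell genes, fatty acid oxidation, sex-linked genes and integrated stress also had a median, mean and test that differed in sign. p53 targets (median 0.04, adjusted p = 0.0974), megakaryocyte genes (-0.14, adjusted p = 0.204), ribosome biogenesis (-0.03, adjusted p = 0.287) and neutrophil genes (0.03, adjusted p = 0.673) were not called.

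In HSCP, the type with the highest expression of stem cell genes, Myl10 rose. Myl10, a myosin light chain gene (chromosome 5, 136693146 to 136701094, plus strand), went from 119 CPM in H2BHiMMPLo to 225 CPM in H2BLoMMPLo, a log2 fold change of 0.98 (SE 0.14, adjusted p = 0.00562 in edgeR). Its log2 CPM was 6.89 ± 0.85 and 7.81 ± 0.42 (SD, n = 3 each), so the libraries overlapped before the name series was taken into account. The adjusted p for Myl10 in HSCP was 0.125 without H2BHiMMPLo replicate 3, 0.189 without H2BLoMMPLo replicate 2 and 1 without the covariate, within a range of 9.52e-13 (no filter on low counts) to 1 over the alternatives. The early response genes followed: Klf2, a quiescence factor of lymphocytes, had a log2 fold change of 1.44 (SE 0.29), Fos 0.96 (SE 0.19) and Jun 0.63 (SE 0.13), each with an adjusted p of 0.11 and so not passing. The histone genes Hist1h2ae at 0.73 and Hist1h2ab at 1.04 stood beside them, and as their copies are near identical the counts of each are uncertain. The comparison rested on 691 and 441 cells in 3 libraries each, since H2BLoMMPLo replicate 4 held 18 HSCP cells and was left out. Of 10154 genes, edgeR called 1, with 439 at an unadjusted p under 0.05 where 508 would be expected by chance, and DESeq2 called 1. With the replicate number as a block the count was 4. It was 14 without H2BHiMMPLo replicate 2, 4 without H2BLoMMPLo replicate 1, and 2 without H2BHiMMPLo replicate 3 or 5 or H2BLoMMPLo replicate 5.

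Stem cell genes were not called as a list in HSCP cells (median -0.02, 11 of 23 above 0, adjusted p = 0.744), with Vwf, a gene of platelet-biased stem cells, at -0.71 (SE 0.30) and Fgd5 at -0.54. The direction of Vwf in HSCP turned with the replicate number as a block (0.049). Oxidative phosphorylation (median -0.03, adjusted p = 0.785), glycolysis (0.01, adjusted p = 0.627), the TCA cycle (0.07, adjusted p = 0.627), fatty acid oxidation (0.03, adjusted p = 0.898) and mTORC1 genes (0.01, adjusted p = 0.907) were not called either. Of 31 lists, 6 were called by camera. Dissociation genes were higher (12 of 16, median 0.40, adjusted p = 1.44e-10, and 0.424 with an estimated correlation; 9 genes adjusted over the list alone, 0 over all genes tested). Lists of stem cell ageing (median 0.04, adjusted p = 0.00441; 3 genes adjusted over the list alone), interferon response (0.08, adjusted p = 0.00712), quiescence (0.09, adjusted p = 0.0416; 2 genes adjusted over the list alone) and ribosome biogenesis (0.06, adjusted p = 0.0434) were higher, each at 0.956 with an estimated correlation. G2M genes were lower (7 of 25 above 0, median -0.21, adjusted p = 0.00111, and 0.956 with an estimated correlation), with Cenpf at -0.46, Ccna2 at -0.42 and Ckap2 on the other side at 0.45. No list was called by fry, and 3 lists were called without H2BHiMMPLo replicate 2, and 3 without H2BLoMMPLo replicate 2. Among lists not called, the median, mean and test differed in sign for mitochondrially encoded genes, ribosomal proteins, oxidative phosphorylation, megakaryocyte genes, integrated stress and cholesterol synthesis.

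Within single types, early response genes passed. Fos was higher in 7 types (IG2, Mast, MDP, MKP, Mono, Multi-Lin-1 and Multi-Lin-2), Jun in 6, Fosb in 6 and Jund in 4. In MKP cells Fos went from 7.78 to 16 CPM (log2 fold change 1.40, SE 0.17), Fosb from 22.6 to 54.8 CPM (1.43) and Jun from 70.5 to 134 CPM (1.01), each with an adjusted p of 0.00118 in edgeR, and for Fosb and Jun all 4 H2BLoMMPLo libraries lay above all 3 H2BHiMMPLo libraries. In Mono cells Fos went from 17.5 to 38.7 CPM (1.18, adjusted p = 0.0016, 4 of 4 libraries above), Zfp36 from 9.42 to 19.1 CPM and Egr1 from 1.74 to 5.59 CPM. Fosb went from 6.52 to 22.9 CPM in ERP1 cells and from 8.07 to 16.8 CPM in IG2 cells. In Mast cells Fos went from 17.8 to 55.4 CPM (2.35, SE 0.38) and Jun from 155 to 315 CPM (1.42). Of the 2 and 3 Mast libraries, H2BLoMMPLo replicate 5 was the only one of the G series, so the covariate took it up and the calls rested on 2 JB libraries per group. The fitted log2 fold change was above 0 in 23 of 23 types for Jun and for Btg2, in 21 of 21 for Fosb and for Zfp36, in 20 of 22 for Fos and in 18 of 19 for Egr1. Of these, Btg2 and Zfp36 passed in 1 type each and Egr1 in 2, and the types come from the same 7 libraries, so they are not separate evidence. Many of these calls ended with 1 library left out. Without H2BLoMMPLo replicate 2, Fos was still called in 1 of the 7 types (Mono; not tested in Mast), Fosb in 2 of 6, Jun in 4 of 6, Jund in 1 of 4, and Egr1, Zfp36 and Btg2 in 0, with log2 fold changes still above 0, such as 1.12 for Fos in MKP and 1.17 for Fos in MDP. Without H2BHiMMPLo replicate 3, Fos was still called in 4, Fosb in 2, Jun in 4, Jund in 2 and Egr1, Zfp36 and Btg2 in 0, and without H2BHiMMPLo replicate 5, Fos in 6, Fosb and Jun in 4 each, Jund in 3, Egr1 in 1 and Zfp36 and Btg2 in 0. Without H2BHiMMPLo replicate 2 the call of Fosb in ERP1 was lost as well as both calls of Egr1, and without H2BLoMMPLo replicate 1 or 5 those of Fosb in ERP1, IG2 and Multi-Lin-1. Without the covariate, edgeR called 0 genes in the 24 types. Weighting 17 types equally gave log2 fold changes of 1.10 for Fosb and 1.05 for Fos in limma, with an adjusted p of 0.084.

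Other genes passed in single types. Platr17 was lower in Mono cells (5.17 against 0.435 CPM) and in proNeu-1 cells (7.73 against 0.402 CPM), below all H2BHiMMPLo libraries in all 4 H2BLoMMPLo libraries, but both calls were lost without H2BHiMMPLo replicate 5 or H2BLoMMPLo replicate 1 or 2, that in Mono also without H2BLoMMPLo replicate 4 and that in proNeu-1 also without H2BHiMMPLo replicate 2. Mcpt8, a protease gene of basophils, was lower in Mast cells (178 against 44.5 CPM, log2 fold change -1.57, SE 0.22). DESeq2 called neither Platr17 nor Mcpt8 in these types. In ERP1 cells Isg15, an interferon-induced gene, was higher (11.3 against 22.1 CPM, adjusted p = 0.0376, 4 of 4 libraries above), a call lost without H2BHiMMPLo replicate 2 or 3 or H2BLoMMPLo replicate 1 or 2 (log2 fold change of 0.93 to 1.13 for Isg15 in ERP1). Retnlg, a neutrophil gene, was called in ERP3 (4.43 against 16.2 CPM) and not without H2BHiMMPLo replicate 5 or H2BLoMMPLo replicate 2 or 5. In cMoP cells 14 genes were called with 2 libraries per group and 1 residual degree of freedom. H2BHiMMPLo replicate 2 was the only JB library there and was taken up by the covariate, so these calls rested on 1 H2BHiMMPLo library against 2. Among them were Scand1 (160 against 292 CPM) and Cd74 (3.34 against 34.9 CPM). For Hist1h2bj, Hist1h4d and Gm42418 in cMoP the fitted sign was opposite to that of the group means. Summed over 24 types, there were 60 calls of a higher and 14 of a lower gene, in 13 types. A gene called in several types counts in each. The sum of 74 became 521 with the replicate number as a block, 131 without H2BHiMMPLo replicate 3, 38 without H2BHiMMPLo replicate 5, 126 without H2BLoMMPLo replicate 1 and 124 without H2BLoMMPLo replicate 4.

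MKP cells of H2BLoMMPLo libraries held more RNA of neutrophil granule genes, and pre-B cells held less. By camera the neutrophil list was called higher in 8 of 24 types and lower in 6, so such changes were not particular to MKP and pre-B. In MKP, Camp, which encodes the antimicrobial peptide cathelicidin, was at 810 and 2440 CPM (log2 fold change 1.18, SE 0.15, adjusted p = 0.00174 in edgeR). The calprotectin genes S100a8 and S100a9 were at 1980 and 5840 CPM (log2 fold change 1.12) and at 2460 and 6890 CPM (1.06). The granule genes Ngp, Lcn2 and Ltf were at 1.17, 1.26 and 1.31 on the log2 scale. The CPM are group means that leave the name series out of account, while the log2 fold changes are fitted with it. The libraries of the groups overlapped for each of these genes. Hba-a1 in MKP went from 2.10 to 6.24 CPM (1.81, SE 0.32), a call lost without H2BHiMMPLo replicate 3 or 5 or H2BLoMMPLo replicate 2. The 25 genes called in MKP were all higher, and the 18 measured genes of the neutrophil list had a median log2 fold change of 0.75 (0.66 within JB libraries and 0.77 within G libraries). In pre-B cells Elane, the neutrophil elastase gene, was at 193 and 53.1 CPM (-2.14, SE 0.29, adjusted p = 0.00347, 4 of 4 libraries below), Prtn3 at 206 and 67.3 CPM, Mpo, the myeloperoxidase gene, at 202 and 94.2 CPM and Anxa3, an annexin gene, at 17.0 and 7.62 CPM. The neutrophil list as a whole was lower in pre-B (16 of 17 below 0, median -0.93, adjusted p = 1.33e-19 by camera, and 0.406 with an estimated correlation), with Fcnb at -3.08, and Hp, called higher in MKP (1.03), was called lower in pre-B (-1.47). Without H2BHiMMPLo replicate 5, Camp in MKP (log2 fold change 1.08), S100a8 in MKP (1.03), Elane in pre-B (-1.48), Prtn3 in pre-B (-0.86) and Mpo in pre-B (-0.62) were no longer called, and neither were Ngp, Lcn2 and Ltf. DESeq2 called none of the 4 pre-B genes. Without H2BLoMMPLo replicate 2 the calls of S100a8, Ngp, Lcn2, Ltf, Prtn3 and Mpo were lost, those of Prtn3 and Mpo also without H2BLoMMPLo replicate 5, that of Mpo also without H2BHiMMPLo replicate 2, those of S100a8 and Ltf also without H2BHiMMPLo replicate 3, and that of Anxa3 without any 1 library but H2BHiMMPLo replicate 3. With the highest doublet scores removed, Camp in MKP was at 0.86 and Elane in pre-B at -0.71. Neither these nor S100a8, Ngp, Lcn2, Ltf, Prtn3 and Mpo were then called. Other genes were still called in MKP: Itgam, Cybb and Ifitm6 beside Fos, Fosb, Jun and Jund. After removal of Scrublet doublets 17 genes were called in MKP, among them Retnlg, Mmp9, Cybb, Ly6g and Itgam. The fold in MKP did not go with the lost calls. The median of the neutrophil list was 0.824 with the highest scores removed (15 of 18 above 0) and 0.501 with Scrublet doublets removed. Why the calls ended was not tested. With Scrublet doublets removed, Elane in pre-B was at -1.71 and no longer called. Without cells of over 50 S100a8 UMIs, pre-B cells had 0 calls (Elane in pre-B at -0.84). The count of genes called in MKP was 5 without H2BHiMMPLo replicate 5, 7 without H2BLoMMPLo replicate 2, 51 and 61 without H2BLoMMPLo replicates 1 and 4, 57 with the replicate number as a block, 7 with the highest doublet scores removed and 4 (Fosb, Jun, Jund and Fos) without cells of over 50 S100a8 UMIs.

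The neutrophil RNA of MKP cells sat in a minority of them. Cells with over 50 S100a8 UMIs made up 19.8% of MKP cells in H2BLoMMPLo replicate 4 (18 of 91, interval 12.2 to 29.4%) and 20.5% in H2BLoMMPLo replicate 5 (23 of 112, 13.5 to 29.2%), against 6.11% in H2BHiMMPLo replicate 5 (8 of 131, 2.67 to 11.7%), which are the libraries of the G series. In JB libraries the shares were 0.767 and 1.03% in H2BHiMMPLo and 1.06 and 2.52% in H2BLoMMPLo. The typical MKP cell held a median of 2 to 14 S100a8 UMIs. With those cells removed, the log2 fold change was -0.43 for Camp in MKP and -0.47 for S100a8 in MKP, which is a removal of cells chosen for such RNA. Cells over the limit were not particular to MKP in G libraries. They made up 9.26% of 54 HSCP cells in H2BHiMMPLo replicate 5, and 16.7% of 18 and 12.5% of 40 in H2BLoMMPLo replicates 4 and 5.

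**Figure D3:**
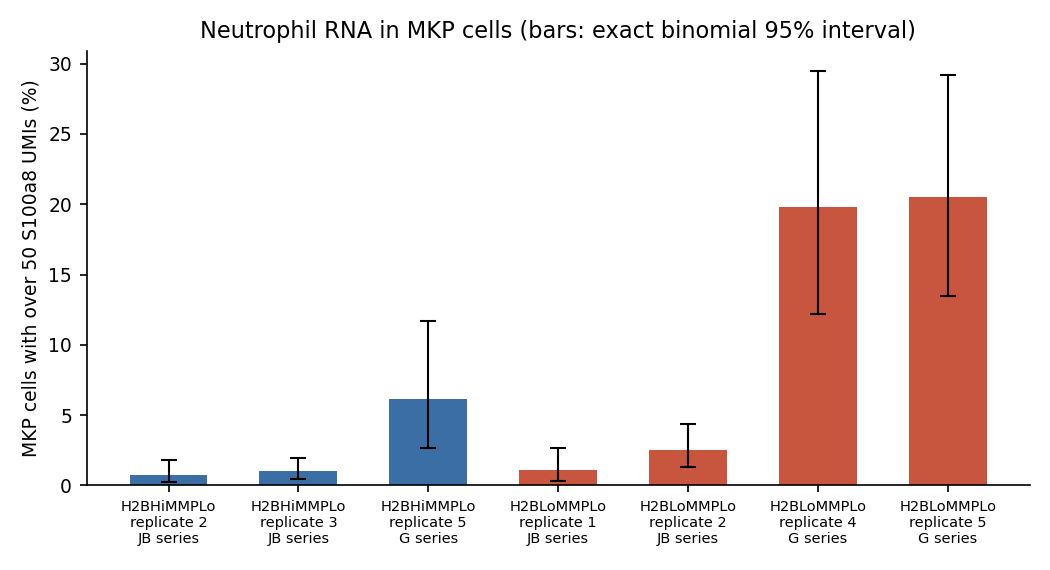
Percent of MKP cells with over 50 S100a8 UMIs (y axis, from 0) in each of 7 libraries. Lines are exact binomial 95% intervals. The bars of H2BLoMMPLo replicates 4 and 5 reach 19.8 and 20.5%, and the other 5 lie between 0.767 and 6.11%.

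Across types, which share the same libraries, some lists kept the direction seen in all cells and others did not. Dissociation genes were called higher in 18 of 23 types and lower in 0, interferon genes in 17 of 24 and lower in 0, stem cell ageing genes in 17 of 21 and quiescence genes in 12 of 23. The ageing and quiescence lists share genes with the dissociation list. MHC genes were called higher in 11 types and lower in 1. G2M genes were called lower in 11 of 22 types and higher in 5, mitochondrially encoded genes lower in 13 of 24 and higher in 2, ribosomal proteins lower in 9 and higher in 0, and oxidative phosphorylation lower in 6 and higher in 2. Stem cell genes, lower in all cells, were called higher in 2 of 17 types and lower in 0, with a median above 0 in 10. S phase genes were called higher in 3 of 23 types and lower in 4. NF-kB genes were called higher in 2 of 22, and the median of their medians was -0.01. Glycolysis was called higher in 3 types and lower in 1, and neutrophil genes higher in 8 of 24 types and lower in 6. With an estimated correlation, the dissociation and ageing lists in Multi-Lin-1 (adjusted p = 0.0459) were the calls that held, and none held in the other types, in HSCP or in all cells.

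Cultured G3 cells differed little from G1 cells, and Serpinb1a and Pf4 stood out among the genes that were higher. Serpinb1a, which encodes an inhibitor of neutrophil proteases, was at 23.8 CPM in G1 (95% Poisson interval 22.5 to 25) and 62.0 CPM in G3 (60.1 to 64.0). Hist1h3c went from 27.9 to 64.8 CPM, Myc from 31.5 to 52.1, the proliferation marker Mki67 from 34.6 to 55.8, Cdk6 from 121 to 181 and the platelet chemokine gene Pf4, under the expression minimum of the ranking, from 11.5 to 37.3. Tiparp, a target of the aryl hydrocarbon receptor, was lower in G3 (114 and 53.5 CPM), as were Ly6a (444 and 223 CPM), the imprinted antisense RNA Airn (74.2 and 42.5 CPM) and Ndnf (62.7 and 38.5 CPM). Across genes, log2 CPM in G3 and G1 had a Pearson r of 0.994, and 3 of 4639 genes differed by over 2-fold, although the interval of 2594 ratios excluded 1 (1597 higher and 997 lower in G3). These intervals cover counting error in 1 library each and not the spread between cultures, and genes are not independent replicates.

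By list, the G3 culture had more division and megakaryocyte RNA and less stem cell, p53 and interferon RNA than G1. G2M genes had a median log2 ratio of 0.66 and megakaryocyte genes one of 0.33, both above all 10000 random lists. Stem cell genes stood at -0.14 (random lists -0.03 to 0.06), with Procr, the endothelial protein C receptor gene, at 187 and 154 CPM and Hlf at 673 and 570 CPM. p53 targets stood at -0.21 with 1 of 20 above 0, where Cdkn1a, the p21 gene, had 603 and 524 CPM. Interferon genes stood at -0.29, S phase genes at 0.06, ribosome biogenesis at 0.07, oxidative phosphorylation at -0.05 (random lists -0.01 to 0.06), glycolysis at -0.04 (-0.03 to 0.07) and cholesterol synthesis at -0.09. Of 29 lists, 6 lay above and 11 below the central 95% of their random lists. Within the 5 clusters with enough cells of both, stem cell and interferon genes were lower and megakaryocyte genes higher in 5 of 5, while p53 targets were lower in 3 and higher in 2. The median over clusters was 0.154 for megakaryocyte genes, -0.099 for stem cell genes, -0.3 for interferon genes and -0.021 for p53 targets. G2M genes were higher in 4 of the 5, from -0.064 to 0.322 with a median of 0.147. This was well under their value over all cells, which itself was 0.282 with CPM + 10. Only 8 to 12 G2M genes were measured in each of clusters 2 to 5. The clusters were formed from the expression of these same cells, so smaller values within them were in part built in.

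G2 and G4 cells lay further from G1, with more division and megakaryocyte RNA and less stem cell RNA. Mki67 was at 229 CPM in G2 and 363 CPM in G4, and Pf4 at 262 and 858 CPM. Procr was at 84.0 and 37.0 CPM, Hlf at 431 and 189, Cdkn1a at 368 and 213, the p53 target Mdm2 at 147 and 90.8, and Ly6a at 241 and 96.3. Meis1, by contrast, was at 906 and 869 CPM against 860 in G1. Relative to G1, the median log2 ratio in G2 and G4 was -0.29 and -0.78 for stem cell genes, 2.69 and 3.03 for G2M genes, -0.71 and -1.51 for p53 targets, 0.71 and 1.59 for megakaryocyte genes (0.781 in G4 with CPM + 10), -0.57 and -0.87 for interferon genes, -0.35 and -1.03 for quiescence genes and 0.30 and 0.75 for ribosome biogenesis. Oxidative phosphorylation stood at 0.00 in G2 and 0.16 in G4, and glycolysis at -0.11 and -0.08. Over 2-fold differences from G1 were seen in 85 of 4795 genes in G2 and 348 of 4957 in G4. Within 4 clusters, stem cell genes and p53 targets were lower and megakaryocyte genes higher in G4 in 4 of 4. The median over clusters was -0.139 for stem cell genes and 0.434 for megakaryocyte genes (0.172 to 0.551). For p53 targets the values ran from -1.527, as large as over all cells, to -0.114 (median -0.445). G2M genes were higher in 3 of the 4 (-0.027 to 0.805, median 0.181). The stem cell, G2M and megakaryocyte values within clusters were far smaller than those over all cells. G4 and G1 cells fell in different clusters: clusters 1 and 8 held 647 and 509 G4 cells against 14 and 28 G1 cells. With under 50 G1 cells, these clusters gave no ratio to G1. As the clusters were formed from this same expression, smaller values within them were in part built in. They do not decide how far the lists changed within like cells. Within 5 clusters, the medians in G2 over G1 were likewise smaller, at 0.312 for G2M genes, 0.138 for megakaryocyte genes, -0.069 for stem cell genes and -0.059 for p53 targets. Ribosome biogenesis genes were lower in 3 of 5 (-0.029). G2 was the shallowest library, and no replicates show how far cultures of 1 condition differ.

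**Figure D4:**
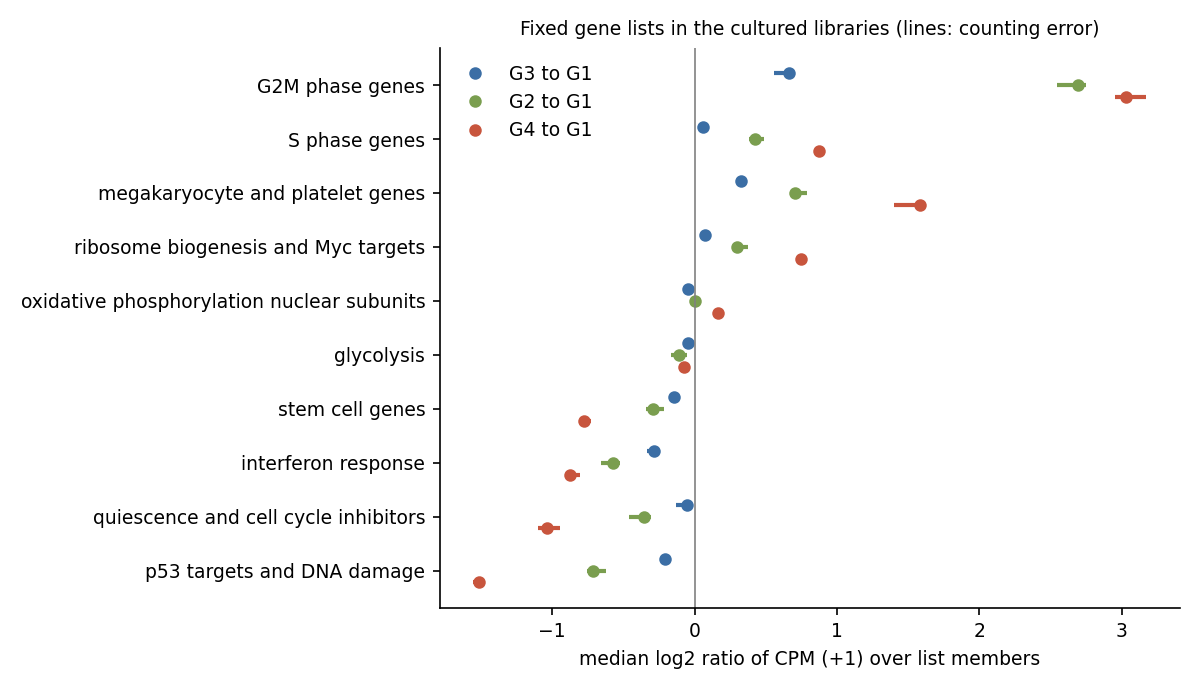
Median log2 ratio of CPM + 1 (x axis) of the members of 10 gene lists in cultured G3, G2 and G4 cells over G1 cells, 1 library each. Lines span the central 95% of 200 Poisson draws of the counts. G2M genes (0.66, 2.69 and 3.03) and megakaryocyte genes lie right of 0, and stem cell genes and p53 targets left of it.

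Xist, the RNA that silences an X chromosome in female cells, was found in some cells of the fresh libraries, in which 15.4 to 40.6% of cells without Xist held no UMI of a Y-linked gene. It was present in 3.00% of cells of H2BLoMMPLo replicate 4 (220 of 7336, interval 2.62 to 3.42%) and in 0.0973 to 1.29% of cells in the other 6 libraries. In H2BLoMMPLo replicate 4 the share was 42.7% in ERP1 cells (interval 33.6 to 52.2%) and 1.59% in preNeu-3 cells, with medians of 14901 and 15716.5 UMIs per cell. With each cell thinned at random to 5000 UMIs, and 831 of 7336 cells under that depth left out, these shares were 42.2 and 1.09%. ERP1 was also above preNeu-3 in H2BHiMMPLo replicate 5 (13.7 and 0.505%) and H2BLoMMPLo replicate 5 (6.67 and 0.657%). The fitted log2 fold change of Xist in all cells was 2.24 (SE 0.97), which was not called. The cultured libraries expressed Xist at 1080 to 1240 CPM. They held almost no RNA of the Y-linked genes Ddx3y (0 to 12 UMIs per library) and Eif2s3y (0 UMIs), whereas most cells of the fresh libraries held Y-linked RNA.

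**Figure D5:**
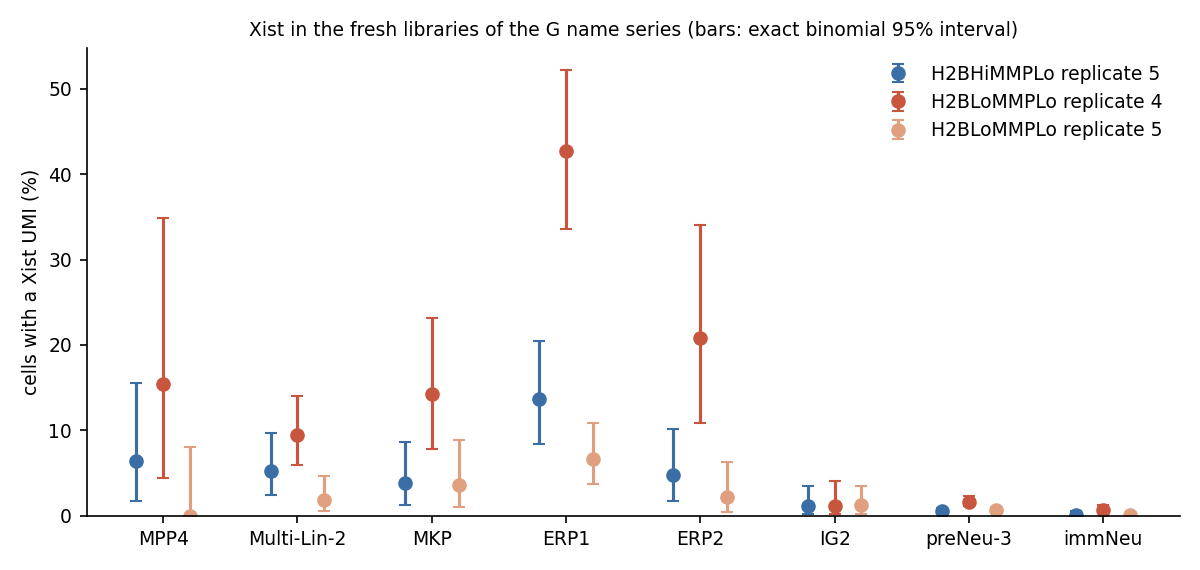
Percent of cells with at least 1 Xist UMI (y axis) in 8 types of H2BHiMMPLo replicate 5 and H2BLoMMPLo replicates 4 and 5. Lines are exact binomial 95% intervals. In H2BLoMMPLo replicate 4 the share is 42.7% in ERP1 and 1.59% in preNeu-3.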

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

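The tests of Xist below, and the removal of cells with Xist, were chosen after the result was seen. Xist is transcribed from the inactive X chromosome of female cells, while Ddx3y and Eif2s3y lie on the Y chromosome. Types of lymphocytes and monocytes were those whose shares stood apart in single libraries.

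Pre-B cells made up 7.66% of H2BLoMMPLo replicate 4, far from the other 4 H2BLoMMPLo libraries, of which the nearest held 2.70%. Macrophage cells made up 1.55% of the same library, where the nearest held 0.539%. In that library they held a median of 1052.5 UMIs, near the 1053 of its barcodes without a type name. In H2BLoMMPLo replicate 1, Regulatory T cell cells made up 1.17% (nearest 0.349%). In H2BHiMMPLo replicate 3, Mono cells made up 1.51% (nearest 2.38%). These are 4 of 50 groups of shares compared, and chance gives a library that stands apart in about 1 in 20 groups. Among 48 other measures of the H2BLoMMPLo libraries, 1 stood apart: in H2BLoMMPLo replicate 4, 66.6% of cells with at least 3 Y-linked UMIs held no Ddx3y UMI, where the nearest library had 21.8%. No explanation of the low Ddx3y was tested.

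H2BLoMMPLo replicate 4 also held the highest share of cells with Xist, and the share differed between types, with ERP1 far above preNeu-3 at like depths. Free Xist RNA would give all types a like share and would leave the Y-linked genes of the receiving cells in place, and the tables argue against it. In every library with at least 10 cells of 3 or more Xist UMIs, the share of cells with no Y-linked UMI was higher in these than in cells with none. The lowest ratio was 1.94, in H2BLoMMPLo replicate 4 (78.9 against 40.6%). It was taken over all types together, and the share with Xist differed between types, so the ratio may in part follow the types. The ratio of 1.94 also fits cells of a female animal among the sorted cells, which may have entered with the pooled animals or from another sample. Which of these routes applied stays open, and no biological explanation was tested. A female animal with a like mix of types would also give all types a like share, so the difference between types was left unexplained. Removing cells with an Xist UMI left Btg2 in all annotated c-Kit cells at a log2 fold change of 0.55, as with all cells.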

How the results depend on the processing

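The fits within JB and within G and the removals of cells with high doublet scores, Xist or neutrophil RNA were chosen after results were seen. Of the values of 117 gene and type pairs under the alternatives, 1745 of 2027 kept their direction and their side of the threshold, 244 kept the direction but not the call, 28 gained a call and 10 reversed. No value of Fos, Fosb, Jun, Jund, Egr1, Zfp36, Btg2 or Klf2 reversed. These genes were followed in all cells, in HSCP or in types where they were called, so most pairs were picked for a high value. Over all types tested, the lowest main value was -0.29 for Fos, -0.20 for Jund and Klf2 and -0.07 for Egr1. For Fosb, Jun, Zfp36 and Btg2 it was above 0. Of results answering a comparison, 103 values were the same by the criterion used (within 1.5 times, for counts) and 36 moved. Shares of types gave 0 under every alternative run, but JB alone, G alone and the replicate block have too few arrangements to give a p under 0.05.

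DESeq2 called 15 genes in all cells, where edgeR called 0 under every other alternative run. For HSCP (1 gene), no filter on low counts gave 43, no covariate 0, the replicate block 4, and removal of the highest doublet scores, JB libraries alone and a minimum of 50 cells 2 each; leaving out 1 library gave 1 to 14. For the types (74 genes), no filter gave 1772, no covariate 0, the replicate block 521, Scrublet doublets removed 596 (of which preNeu-1 gave 507), JB alone 142 and G alone 1110; leaving out 1 library gave 38 to 131. G alone has 1 H2BHiMMPLo library, which is assumed to vary like the others, so no conclusion is drawn from its count. Of the 74 calls, 74 were shared with no filter, 38 with DESeq2, 61 with RLE factors, 53 with the replicate block and 21 without H2BHiMMPLo replicate 5. In HSCP, where 6 lists were called, the total was 3 without the covariate, 0 with an estimated correlation, 0 with fry and 3 to 7 with 1 library left out. In all cells, where 15 lists were called, the total was 0 with an estimated correlation, 0 with fry and 13 to 18 with 1 library left out. The cause was not tested. HSCP could not be fitted in G alone, and the replicate block could be fitted in 19 of 24 types.

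Directions reversed for Mki67 in all annotated c-Kit cells without the covariate (0.004), Eno1 in all annotated c-Kit cells in G alone (-0.017), and, with the replicate block, Scd1 in all annotated c-Kit cells (-0.175) and Vwf in HSCP (0.049). None of these was called, and the cause was not tested. In MKP, removal of cells with over 50 S100a8 UMIs reversed Camp in MKP (-0.431), Lcn2 in MKP (-0.292), S100a8 in MKP (-0.471), Pglyrp1 in MKP (-0.068), Ltf in MKP (-0.811) and Ngp in MKP (-0.472), and it takes out cells chosen for such RNA. In culture, CPM + 10 in place of CPM + 1 drew medians toward 0, as a larger pseudocount does for genes with low counts: stem cell genes -0.097 in G3 and -0.543 in G4 over G1, G2M genes 0.282 and 2.135, megakaryocyte genes 0.253 and 0.781, and p53 targets -1.317 in G4. The stroma list in G4 over G1 went from 0.434 to -0.09 when haemoglobin, ribosomal protein and mitochondrial genes were left out of the total. HSCP held 18 to 350 cells per library, and some other types rested on fewer cells, such as cMoP with 82 and 130 cells in 2 libraries per group.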

Other observations

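The tests of the name series and of free neutrophil RNA, and the removals of cells they are set beside, were chosen after results were seen. Fos, Fosb, Jun, Egr1, Zfp36 and Btg2 respond to growth factors, cytokines and to the stress of taking cells out of a tissue. Their fitted log2 fold change was above 0 for Jun and Btg2 in 23 of 23 types and for Fosb and Zfp36 in 21 of 21, but most of these values did not pass: Fos was called in 7 of 22 types, Jun and Fosb in 6, and Btg2 and Zfp36 in 1, and without H2BLoMMPLo replicate 2 Fos was still called in 1, Fosb in 2, Jun in 4 and Btg2 and Zfp36 in 0. The types come from the same 7 libraries. Camp, S100a8, S100a9, Ngp, Lcn2 and Ltf, which neutrophils store in granules and cytosol, were higher in MKP cells of H2BLoMMPLo, and Elane, Prtn3, Mpo, Fcnb and Hp, also neutrophil genes, were lower in pre-B cells.

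The early response members of the dissociation list had a median log2 fold change of 0.603 in all cells. The tables argue against a difference between the name series as the cause, since the median was 0.609 within JB and 0.701 within G. They also argue against cells with high doublet scores, neutrophil RNA or an Xist UMI, as the lowest median after their removal was 0.541. Removing cells with an Xist UMI left any cells of another male animal, and female cells with no Xist UMI, in place. A difference between the pooled animals therefore stays open. Stress of handling that also induces heat shock genes stays open: the heat shock members had a median of -0.134, but this moved between -0.308 and 0.14 with 1 library left out and was 0.143 within JB and -0.537 within G. A stress that induces no heat shock genes, and a difference in signalling between the H2BLoMMPLo and H2BHiMMPLo populations, may each underlie the pattern and were not tested. Chance was not excluded either. The dissociation list was called higher in 15 of the 17 types with every library at the minimum of cells. Of 34 splits, 3, the real one included, gave as many, the highest other 16. The other splits at 15 and 16 grouped H2BLoMMPLo replicate 4 with H2BHiMMPLo replicates 2 and 3, and with 2 and 5. Another split set H2BLoMMPLo replicates 1, 2 and 5 against all other libraries. There the list was higher in these 3 H2BLoMMPLo replicates in 17 types.

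The neutrophil genes of MKP cells had a median log2 fold change of 0.746, which became -0.175 without MKP cells of over 50 S100a8 UMIs, but stayed at 0.824 with the highest doublet scores removed and 0.501 with Scrublet doublets removed. In 7 of 7 libraries those cells held at least 1.2 times the total UMIs and 0.5 times the megakaryocyte UMIs of other MKP cells, but neither this nor the -0.175 decides whether MKP cells were caught in 1 droplet with a neutrophil, since the removed cells were chosen for S100a8 and a limit in UMIs favours deeper cells. Free neutrophil RNA is argued against in JB, where the median of S100a8 UMIs per MKP cell was lower in both H2BLoMMPLo libraries (difference -1.5), and stays open in G, where it was 10 in H2BHiMMPLo replicate 5 and 5 and 14 in H2BLoMMPLo replicates 4 and 5 (difference -0.5). Scrublet ranked 26.1 and 27.8% of those cells among its highest scores in H2BLoMMPLo replicates 5 and 4, against 75 to 100% in the other libraries, and doublets, attached cells and MKP cells that express the genes themselves stay open. The neutrophil list's difference between MKP (0.758) and pre-B cells (-0.688) was 1.45, with an exact permutation p of 0.0571 over 35 splits, so it did not pass.

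Splits of the same libraries were compared with the real one, which each count below includes, and chance was excluded for no result tested. For genes in all cells there was nothing to test, as the real count was 0, which every split reaches (34 of 34), and the highest gave 99, with H2BHiMMPLo replicate 2 and H2BLoMMPLo replicates 1 and 5 on one side. A count so far above the real one may point to a structure of the libraries other than their population, but it came from 1 split and was not tested. For the genes summed over 17 types, 8 of 34 splits gave at least the real 54, the highest 121, and for the lists in all cells 8 of 34 gave at least 15, the highest 19. The split of JB from G libraries could not be fitted with its own covariate. Of the 12 splits that part both pairs of replicate numbers, as the real one does, 2 gave as many genes over types (highest other 65) and 4 as many lists. In HSCP the 10 splits are too few for a share under 0.05: the real count of genes was 1 and the highest other 10, with 9 splits as large, and of lists 6 and 11, with 8 splits as large.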
